A study of Mus musculus with 42 samples.

How the data were processed

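RNA was taken from ear skin, from aorta between the heart and the iliac bifurcation with perivascular fat removed, and from liver flushed with buffer, per the labels' protocols. Per the labels, K14-Rac1V12 mice were randomly assigned to an omega-3-deficient diet, an EPA-rich diet or a DHA-rich diet, both stated at 3 g per kg of diet and matched to a human dose of 4 g per day; the label text of the DHA dose names EPA, and it is read here as DHA. The labels give 5 mice assigned per diet and 4 to 5 per group for RNA, so the libraries of a group are separate mice; the labels give neither sex nor batch and tie no library of 1 tissue to a library of another. The data do: the libraries with high Xist (over 200 CPM) have the same diet and replicate number in every tissue, and DHA 3 has 15.9 to 49.9 CPM of 4 Y-linked genes in the 3 tissues, against 69.1 to 338 in the others without high Xist, so replicate numbers appear to follow the mouse, which was not checked in this way for OD. Over 1625 genes the deviations from the group means correlated at a mean of 0.0589 between tissues for libraries of the same number (12 of 42 pairs over 0.1). The mean was -0.0158 for the other pairs of a diet, which adds no support, since deviations within a group sum to 0. Of the numbers with high Xist, EPA 1 and DHA 1 had correlations of -0.200 to 0.0191 between tissues, and EPA 5 of 0.142 to 0.257. Libraries were made from 10 ng of RNA with a QIAseq UPX 3' kit, which tags each sample and each RNA molecule, and sequenced on a NextSeq500, per the labels' protocols. The aligner, the counting program and whether molecular tags were collapsed are not given in the sources used here; the submitters' processing notes name the build GRCm38.p6 and edgeR, without a version.

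The deposited table of counts, named total counts per the file headers, holds whole-number counts of 48709 genes in 42 libraries and was used for every test. The deposited normalised values carry the heading CPM per the file headers, but the columns sum to between 513430 and 1767790, so they are treated as a score in the authors' own scale; each column is a fixed multiple of its counts and lies within a relative difference of 0.0414 of CPM computed here with TMM over all libraries. Of the gene identifiers 48349 are in GENCODE M21, 46199 with the same symbol, and these hold 99.9774% of counts; coordinates are from that annotation. No pair of libraries of a group was a duplicate of another (chi-square per degree of freedom of at least 1.46 over 78 pairs). Median depth was 91629 counts in skin, 452412 in aorta and 484510 in liver.

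Each tissue was fitted apart with its 3 diets in edgeR 4.0.16 (R 4.3.3): filterByExpr on diet with its minimum count of 10, TMM scaling, the quasi-likelihood F test and Benjamini-Hochberg adjustment within each contrast, with adjusted p under 0.05 as the threshold. The filter left 2133 genes in skin, 6538 in aorta and 5018 in liver. The contrasts were EPA minus OD, DHA minus OD, EPA minus DHA and all 3 diets together. Log2 changes are those of the fit, standard errors are the change divided by the square root of F, and means and SDs of genes are of CPM scaled by TMM with the counts of the tested genes as the total; Xist, Y-linked, Acta1 and library floors are in CPM of all counts, as are the Mup values of the closing section. Whether a diet effect differs between tissues was tested with 2 degrees of freedom in a fit of all 9 groups, with tissues as independent. In a later fit libraries of the same diet and number were taken as a mouse and used as a block. The Xist and Y-linked match behind this block was not made for OD. For 48 gene lists fixed in advance, those with at least 5 tested members (28 in skin, 33 in aorta and 34 in liver) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, at the preset correlation of 0.01, with an estimated correlation, and with fry. Some list members belong to more than 1 list, so the lists are not independent.

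The genes named were chosen by a rule: the 12 with the smallest p among the higher and among the lower genes past the threshold, or the 5 with the smallest p where fewer than 5 passed; up to 4 members with the smallest p of each list that camera called; and genes chosen for each tissue whatever their result. Predicted genes, Rik clones and pseudogenes were counted but not named, and of the list members not all are printed. The genes chosen for each tissue that had too few counts to be tested were Lcn2, Defb14, Cxcl5, Fads1, Fads2 and Alox12b in skin, Icam1, Ccl2, Abcg1 and Fads2 in aorta and Pnpla3, Acot1 and Fgf21 in liver. Il36a and Flg, also chosen for skin, were not found under these symbols in the deposited counts. The design, the lists, the rule and the main alternatives were written before the data were examined; later additions are named as such in the closing section.

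The alternatives were DESeq2 1.42.0 (its test and its size factors), no filter, a robust prior, limma with quality weights, limma on the deposited normalised values with a pseudocount of 1, the tag number of the library modulo 12 as a block, a fit of 42 libraries, a fit of 2 diets, an adjusted p under 0.1, and each library left out. The scripts were tested on simulated negative binomial counts with 200 changed genes, where 5 unchanged genes of 78 called were called in skin, 4 of 110 in aorta, 2 of 92 in liver and 3 of 105 for differences between tissues. Changes of 1.5-fold were recovered in 7.81%, 14.3% and 10.8% of cases in skin, aorta and liver, 2-fold changes in aorta in 59.7% and 4-fold changes in aorta in 88.9%, and differences between tissues of 2-fold and 4-fold in 18.3% and 79.4%. The values expected where contrasts share the OD libraries came from 20 simulated data sets without a diet effect. Each gene was drawn independently in them, so they lack variation that genes share between libraries.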

Results

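Gene expression was measured in ear skin, aorta and liver of K14-Rac1V12 mice. In this transgenic line an active form of the small GTPase Rac1 is expressed from the keratin 14 promoter of basal keratinocytes, and the skin develops psoriasis-like inflammation. Per the labels, mice aged 14 weeks that had eaten an omega-3-deficient diet (OD) for 2 weeks were randomised to 3 diets for 12 weeks. They stayed on OD or ate a diet rich in eicosapentaenoic acid (EPA) or in docosahexaenoic acid (DHA). Both are long-chain omega-3 fatty acids, and DHA has the longer chain and an additional double bond. The comparisons ask how each fatty acid changes expression in inflamed skin, vessel wall and liver, and whether EPA and DHA differ at the same stated dose of 3 g per kg of diet. The 42 libraries form 9 groups, with 4 OD, 5 EPA and 5 DHA libraries in each tissue. The libraries of a group are taken as separate mice, from the numbers of mice that the labels give.

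Total counts per library ran from 40157 to 220488 in skin, from 179795 to 717508 in aorta and from 343824 to 768532 in liver. A count of 3 corresponded to 13.6 to 74.7 CPM (counts scaled to equal library totals) in skin, 4.18 to 16.7 in aorta and 3.90 to 8.73 in liver. Transcripts rarer than this mostly had fewer counts than the filter's minimum of 10. The CPM of single genes below are scaled to the counts of the tested genes of the tissue, on average 71.5% of all counts in skin, 94.3% in aorta and 95.3% in liver. OD livers were sequenced more deeply (671271 ± 96218 counts, SD, n = 4) than EPA livers (479164 ± 17866, n = 5) and DHA livers (444004 ± 59017, n = 5). An exact permutation test gave p = 0.00794 for each, or 0.0714 after Benjamini-Hochberg adjustment over 18 such tests. Mitochondrially encoded transcripts took 18.4 ± 7.14% of counts in OD aortas (SD, n = 4), 23.4 ± 1.99% in EPA aortas and 25.2 ± 3.41% in DHA aortas (n = 5 each). Against OD the exact permutation p was 0.198 for EPA and 0.127 for DHA. Xist, the transcript that silences an X chromosome in female cells, exceeded 200 CPM in 3 of the 14 libraries of each tissue, named libraries with high Xist here. Of these 2 were on EPA, 1 on DHA and 0 on OD, with the same replicate numbers in every tissue. They held 0 to 2 counts of 4 Y-linked genes together, the pattern of female mice, and each OD library held 13 to 132. Sex, which the labels do not give, is thus partly confounded with diet in the contrasts against OD. Albumin mRNA (Alb), made by hepatocytes, had 44 to 99 counts in every skin library and 69 to 204 in every aorta library.

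**Figure D1:**
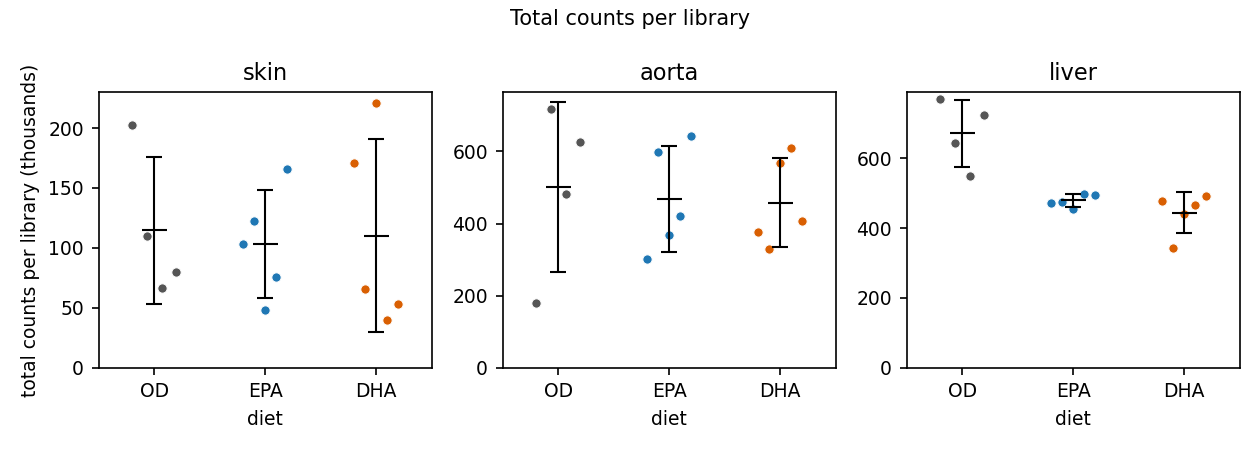
Total counts per library (y axis, in units of 1000 counts) by diet (x axis) in skin, aorta and liver, with 1 point per library and bars at the mean ± SD. Skin libraries lie between 40157 and 220488 counts, and the OD livers, at 549635 counts or more, lie above the EPA and DHA livers.

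In the aorta, 319 of 6538 tested genes differed between DHA and OD, 280 higher and 39 lower on DHA (edgeR's quasi-likelihood test). The median absolute change was 0.81 on the log2 scale. Nuclear genes of oxidative phosphorylation, the mitochondrial pathway that makes ATP, rose together, with 57 of 75 measured members higher and 0 lower. With p adjusted over the list alone 72 were higher (adjusted p = 0.0835 with an estimated correlation). The complex I subunits Ndufc2 and Ndufv3 rose by 0.86 ± 0.14 and 0.83 ± 0.14 (log2 ± SE), the complex III subunit Uqcr11 by 0.84 ± 0.15 and the ATP synthase subunit Atp5k by 0.82 ± 0.15. Of fatty acid synthesis genes and SREBP1 targets 15 of 27 rose and 0 fell, with 19 higher adjusted over the list alone (adjusted p = 0.111 with an estimated correlation). G6pdx and Pgd, which make NADPH in the pentose phosphate pathway, rose by 1.41 ± 0.20 and 1.32 ± 0.23. The fatty acid elongase Elovl6 rose by 1.33 ± 0.22 and Agpat2, an enzyme of triglyceride synthesis, by 1.08 ± 0.16. Of fatty acid oxidation genes and PPAR alpha targets 20 of 46 rose and 0 fell, with 29 higher adjusted over the list alone (adjusted p = 0.111 with an estimated correlation). They include the beta-oxidation enzymes Hadha (0.92 ± 0.17), Hadh (0.74 ± 0.13) and Cpt2 (0.98 ± 0.19) and the lipid droplet protein Plin2 (1.09 ± 0.22). G6pdx (ENSMUSG00000031400, GRCm38 chromosome X, 74409483 to 74429194) had the smallest p, with 39.5 ± 6.98 CPM on OD (SD, n = 4) and 107 ± 9.93 on DHA (n = 5). Its adjusted p was 0.00118 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

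Markers of brown adipocytes, the fat cells that burn lipid for heat, rose in the same aortas, with 9 of 18 measured members higher and 0 lower on DHA. With p adjusted over the list alone 14 were higher (adjusted p = 0.111 with an estimated correlation). Ucp1, the uncoupling protein of brown fat (ENSMUSG00000031710, GRCm38 chromosome 8, 83290352 to 83298452), rose from 829 ± 329.7 to 1971 ± 327 CPM (1.25 ± 0.26 log2). The proton channel gene Otop1 rose by 1.46 ± 0.22, the muscle and brown fat cytochrome oxidase subunits Cox8b and Cox7a1 by 1.08 ± 0.21 and 1.21 ± 0.24 and mitochondrial Letmd1 by 1.06 ± 0.19. Of white adipocyte markers 9 of 25 rose and 0 fell, with 18 higher adjusted over the list alone (adjusted p = 0.112 with an estimated correlation). Examples are Gpd1 (1.32 ± 0.25), Dgat2 (0.75 ± 0.16) and Acsl1 (0.70 ± 0.19). The adipocyte hormone Adipoq did not pass (0.49 ± 0.20, adjusted p = 0.176 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the sebaceous gland list 6 of 13 members rose and 0 fell, with 9 higher and 1 lower adjusted over the list alone (adjusted p = 0.0835 with an estimated correlation). Its members Elovl3 (1.61 ± 0.37), Fasn (0.98 ± 0.24), Cidea (0.76 ± 0.20) and Ldhb (0.90 ± 0.21) are genes that adipocytes also express. The labels state that perivascular fat was removed from the aortas. Adipocyte transcripts were still present in every aorta on every diet, with Ucp1 at 441 to 2233 CPM of all counts and Adipoq at 188 to 436. Ucp1 was at 0 to 6.44 in the livers.

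Other metabolic genes rose on DHA. Of the polyunsaturated fatty acid list 7 of 21 members rose and 0 fell, with 8 higher adjusted over the list alone (adjusted p = 0.111 with an estimated correlation). Among them was Hsd17b12 of the elongation complex (0.93 ± 0.22). The desaturase Fads1 did not pass (-0.39 ± 0.25). Of the gluconeogenesis and insulin response list 4 of 20 members rose and 0 fell, with 5 higher adjusted over the list alone (adjusted p = 0.117 with an estimated correlation). They were the insulin-regulated glucose transporter Slc2a4 (1.14 ± 0.25), Pck1 (0.81 ± 0.21), Pygl (0.98 ± 0.28) and Gys2 (1.18 ± 0.34). The fatty acid transporter Cd36 rose by 0.74 ± 0.18, the phospholipase Ddhd2 by 1.06 ± 0.17, the acyl-CoA synthetase Acsl5 by 1.34 ± 0.22 and the glycolytic enzyme Pfkl by 1.25 ± 0.21. Cib2 (0.96 ± 0.15) and Paqr9 (1.75 ± 0.28) were also among the 12 rising genes with the smallest p. Fabp4, the fatty acid binding protein of adipocytes and macrophages, was at 0.73 ± 0.23 and the PPAR targets Pdk4 and Angptl4 at 0.83 ± 0.26 and 0.79 ± 0.37 without passing. Neither the cholesterol transporter Abca1 (0.13 ± 0.21) nor the prostanoid synthases Ptgis (-0.17 ± 0.16) and Ptgs1 (-0.19 ± 0.30) passed.

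Immediate early and heat shock genes, which respond within minutes to stimuli and stress, fell in DHA aortas, with 8 of 29 members lower and 0 higher. With p adjusted over the list alone 16 were lower and 2 higher, and this list passed with an estimated correlation too (adjusted p = 0.0152 with an estimated correlation). The MAP kinase phosphatase Dusp1 fell from 340.3 ± 56.1 to 174 ± 30.6 CPM (SD, n = 4 and 5), a log2 change of -0.96 ± 0.18. The matricellular genes Cyr61 and Ctgf changed by -1.44 ± 0.27 and -0.92 ± 0.20, Btg2 by -0.93 ± 0.23 and the AP-1 subunit Jun by -0.85 ± 0.21. The nuclear receptor Nr4a1 changed by -1.71 ± 0.42, with 324 CPM in OD aorta 4 and at most 85.7 in the other OD aortas. Outside that list, the thrombin receptor F2r changed by -0.92 ± 0.21 and the macrophage lectin Lgals3 by -1.50 ± 0.35. Cpe, Cytl1 and Pbxip1 changed by -0.65 ± 0.13, -0.79 ± 0.20 and -0.59 ± 0.15. Of the smooth muscle list 2 of 27 members fell, with 11 lower adjusted over the list alone (adjusted p = 0.159 with an estimated correlation). They were Susd5 (-0.68 ± 0.18) and Smtn (-0.60 ± 0.16). The contractile genes Myh11 (-0.59 ± 0.18) and Acta2 (-0.63 ± 0.21) did not pass. Of 36 fibroblast members 0 passed, 0 adjusted over the list alone, with a median of -0.28 (adjusted p = 0.379 with an estimated correlation). Pi16 and Fn1 were at -0.86 ± 0.26 and -0.52 ± 0.17. Of 13 mitochondrially encoded RNAs 0 passed, 0 adjusted over the list alone, with a median of 0.62 (adjusted p = 0.289 with an estimated correlation).

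The 12 lists just given are those that camera called for DHA against OD at its preset correlation of 0.01. An exact permutation test of each list's mean over libraries, added after the data had been seen, passed 11 of 33 lists. The adjusted p was 0.0262 for 10 of them, from p = 0.00794, the smallest that 4 against 5 libraries can give in an exact test, and 0.0476 for smooth muscle. The oxidative phosphorylation mean was 8.59 ± 0.21 on OD and 9.25 ± 0.03 on DHA (log2 CPM, SD, n = 4 and 5). That of brown adipocyte markers was 6.74 ± 0.46 and 7.57 ± 0.08, and that of immediate early genes 7.31 ± 0.13 and 6.70 ± 0.13. Over all tested genes the DHA and OD libraries did not overlap in 7.63%, where chance gives 1.59%. The skeletal muscle list was not called for DHA (adjusted p = 0.555 with an estimated correlation), with 0 of 12 members passing and 3 higher adjusted over the list alone. Its median was 1.495 in the fit and 1.12 as differences in mean log2 CPM, with Acta1 at 213 and 147 CPM of all counts in DHA aortas 3 and 5 and at most 33.1 in OD aortas. With its mean as a covariate 204 of the 319 genes still passed, 45 oxidative phosphorylation genes among those called. With the mean of the brown adipocyte list as a covariate 0 genes passed, and without the libraries with high Xist 273. The count fell to 70 without OD aorta 4, 128 without OD aorta 3, 195 without DHA aorta 1, 116 with the 3 tissues in a common fit and 188 with counts thinned to the lowest total. Scaled by total counts alone, the median change of all aorta genes was -0.12 for EPA and -0.21 for DHA, against -0.01 and -0.03 with TMM, and no aorta list named here turned direction.

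**Figure D2:**
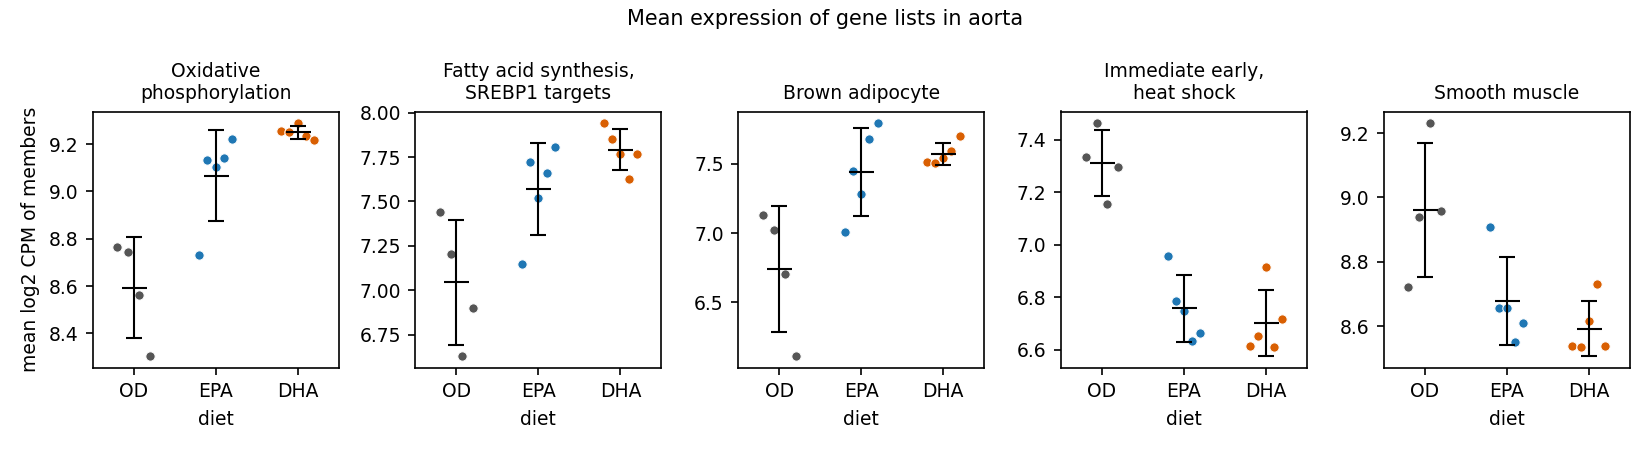
Mean log2 CPM of the members of 5 gene lists (y axis) by diet (x axis) in aorta, with 1 point per library and bars at the mean ± SD. The oxidative phosphorylation mean is 8.59 on OD and 9.25 on DHA, and the immediate early and heat shock mean is 7.31 on OD and 6.70 on DHA.

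**Figure D3:**
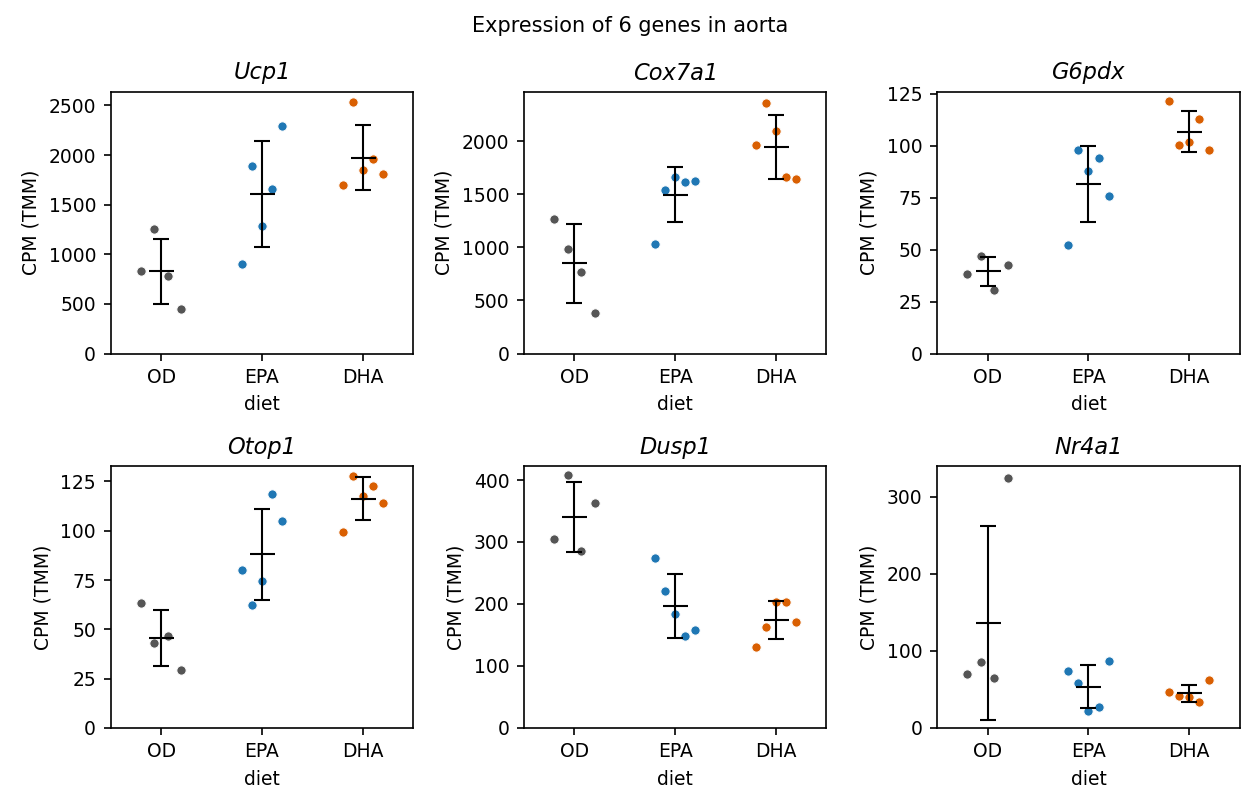
Expression (y axis, CPM scaled by TMM) of 6 genes by diet (x axis) in aorta, with 1 point per library and bars at the mean ± SD. Ucp1 averages 829 CPM on OD and 1971 on DHA, and Dusp1 340.3 and 174.

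EPA against OD gave 18 aortic genes, 15 higher and 3 lower on EPA (edgeR's quasi-likelihood test), with 822 genes at unadjusted p under 0.05. The phospholipase Ddhd2 rose from 77.6 ± 11.3 to 167 ± 25.3 CPM (SD, n = 4 and 5), a log2 change of 1.10 ± 0.17. Its adjusted p was 0.00668 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of other lipid genes, Agpat2 rose by 1.00 ± 0.16, Elovl6 by 1.02 ± 0.22, G6pdx by 1.04 ± 0.20, Pgd by 1.24 ± 0.23 and the retinol-binding protein Rbp7 by 2.37 ± 0.43. Mitochondrial genes that rose were Ndufc2 (0.74 ± 0.14), Ndufv3 (0.66 ± 0.14), cytochrome c1 (Cyc1, 0.68 ± 0.14) and Chchd10 (0.90 ± 0.18). Cpt2 and Hadha of fatty acid oxidation rose by 0.90 ± 0.19 and 0.77 ± 0.17, brown fat Otop1 by 1.06 ± 0.22 and Cib2 by 0.81 ± 0.15. The 3 genes that fell were Btg2 (-1.11 ± 0.23), Ctgf (-0.95 ± 0.20) and Dusp1 (-0.82 ± 0.18), all on the immediate early list. Of that list 3 of 29 members passed, with 15 lower and 2 higher adjusted over the list alone (adjusted p = 0.00734 with an estimated correlation). Over all tested genes the EPA and OD libraries did not overlap in 3.10%, where chance gives 1.59%.

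Oxidative phosphorylation had 3 of 75 members higher over all genes and 62 adjusted over the list alone (adjusted p = 0.115 with an estimated correlation). Fatty acid synthesis had 4 of 27 members higher over all genes and 16 adjusted over the list alone (adjusted p = 0.115 with an estimated correlation). The PPAR alpha target list had 2 of 46 members higher over all genes and 28 adjusted over the list alone (adjusted p = 0.115 with an estimated correlation). Polyunsaturated fatty acid synthesis had 1 of 21 members higher over all genes and 8 adjusted over the list alone (adjusted p = 0.115 with an estimated correlation). The brown adipocyte list had 1 of 18 members higher over all genes and 15 adjusted over the list alone (adjusted p = 0.115 with an estimated correlation). Ucp1 was at 0.96 ± 0.26 without passing (adjusted p = 0.0724 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The white adipocyte list had 0 of 25 members higher over all genes and 17 adjusted over the list alone (adjusted p = 0.115 with an estimated correlation). The sebaceous gland list had 0 of 13 members higher over all genes and 7 adjusted over the list alone (adjusted p = 0.115 with an estimated correlation). Smooth muscle genes had 0 of 27 members lower and 1 adjusted over the list alone (adjusted p = 0.218 with an estimated correlation). Camera also called 6 lists in which 0 members passed, 0 adjusted over the list alone. Their medians were -0.24 for fibroblasts (adjusted p = 0.397 with an estimated correlation) and 1.37 for skeletal muscle (adjusted p = 0.417 with an estimated correlation). For skeletal muscle the median of differences in mean log2 CPM was 0.53, with Neb at 2.05 ± 0.77. Its actin Acta1 was at 358 CPM of all counts in EPA aorta 2 and at most 21.8 in the other EPA aortas. With the mean of this list as a covariate 6 of the 18 genes still passed, at a median of 0.95 (from 0.97), and 0 oxidative phosphorylation genes. Medians were 0.37 for cholesterol synthesis (adjusted p = 0.218 with an estimated correlation) and 0.35 for gluconeogenesis and insulin response (adjusted p = 0.268 with an estimated correlation). Mitochondrially encoded RNA had a median of 0.39 (adjusted p = 0.367 with an estimated correlation) and the unfolded protein response -0.16 (adjusted p = 0.367 with an estimated correlation). Fabp4 (0.67 ± 0.23), Pdk4 (0.72 ± 0.26), Angptl4 (0.69 ± 0.37), Abca1 (-0.05 ± 0.21), Ptgis (-0.16 ± 0.16) and Ptgs1 (-0.02 ± 0.29) did not pass. In the exact permutation test of list means 0 of 33 lists passed for EPA, with 10 at unadjusted p under 0.05 and a smallest adjusted p of 0.146.

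The count of 18 genes depended on every library. It was 125, 62, 0 and 2 without OD aortas 1 to 4, and 257, 6, 2, 2 and 1 without EPA aortas 1 to 5. Without DHA aortas 1 to 5, which share the estimate of spread, it was 9, 7, 8, 7 and 8. DESeq2 gave 186 genes, limma with quality weights 192 and limma on the deposited normalised values 8. With the DHA libraries left out of the fit 0 passed, and with the brown adipocyte covariate 0. A test over the 3 diets together called 165 aortic genes (edgeR's quasi-likelihood test). It called 5 without OD aorta 4, 7 without OD aorta 3 and 288 without EPA aorta 1. Without DHA aortas 1 to 5 it called 71, 56, 71, 87 and 85.

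Between EPA and DHA themselves, 0 of 6538 aortic genes passed edgeR's quasi-likelihood test, with 226 at unadjusted p under 0.05. DESeq2, limma with quality weights and limma on the deposited normalised values gave 0 as well. The smallest p values belonged to Rnaset2a (-0.76 ± 0.19), Rnf20 (-0.81 ± 0.21), Zfp706 (0.56 ± 0.15), Mfsd14b (-0.98 ± 0.28) and Elof1 (-0.65 ± 0.19). The 95% intervals of the log2 difference EPA minus DHA were -0.72 to -0.01 for G6pdx, -0.77 to 0.20 for Ucp1, -0.72 to 0.10 for Elovl6 and -0.53 to 0.17 for Cd36. A missed threshold does not show that these structurally related fatty acids act alike, and differences up to these limits are not excluded. Oxidative phosphorylation genes had a median of -0.18 over 75 members, fatty acid synthesis genes -0.17 over 27 and PPAR alpha targets -0.11 over 46. In each list 0 members passed, 0 adjusted over the list alone. Camera called these 3 lists lower on EPA at its preset correlation, and the call was lost for each (adjusted p = 0.975 with an estimated correlation). In both comparisons 14 higher and 3 lower genes passed, a number that the shared OD libraries raise by themselves. Across genes, which are not independent replicates, the log2 changes on EPA and on DHA had Pearson r = 0.78 and covariance 0.111. Both use the same OD libraries, and simulated groups without any effect gave r = 0.53 and covariance 0.0442. These simulations drew each gene independently and lack variation that genes share between libraries. Values above the simulated ones therefore do not show that the fatty acids share effects. With 2 different OD libraries for each fatty acid r was 0.32 and the covariance 0.0637.

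In skin, the site of the disease, 0 of the measured psoriasis-associated genes passed on either omega-3 diet. The list fixed for the IL-17 and IL-23 axis had fewer than 5 tested members in skin, so it was not tested as a list. Keratin 14 (Krt14), whose promoter drives the transgene, was at 19335 ± 4349 CPM on OD (SD, n = 4), 19938 ± 4881 on EPA and 19459 ± 6447 on DHA (n = 5 each). Krt6a, a keratin of activated epidermis, differed from OD by -0.21 ± 0.39 on EPA and -0.16 ± 0.39 on DHA (log2 ± SE), Krt6b by 0.09 ± 0.41 and 0.09 ± 0.41 and Krt16 by 0.15 ± 0.38 and -0.03 ± 0.38. The calprotectin subunits S100a8 and S100a9, abundant in psoriatic epidermis and neutrophils, differed by 0.07 ± 0.39 and 0.44 ± 0.40 on EPA and 0.49 ± 0.39 and 0.69 ± 0.40 on DHA. On EPA and DHA the cytokine Il1b differed by 0.54 ± 0.59 and 0.64 ± 0.60, the prostaglandin synthase Ptgs2 by -0.16 ± 0.56 and -0.37 ± 0.58 and the lipogenic desaturase Scd1 by -0.66 ± 0.32 and -0.35 ± 0.33. Rac1, the gene of the transgene, differed by -0.59 ± 0.47 and -0.34 ± 0.46, and without OD skin 1 by 0.12 and 0.38, in the other direction. DHA skin 1 was also high, at 4068 CPM against 787 to 1974 in the other DHA skins, so neither direction holds. The psoriasis epidermal activation list had 0 of 28 members passing on either diet, 0 adjusted over the list alone, with medians of -0.02 on EPA and 0.16 on DHA in the fit. The medians of its differences in mean log2 CPM were -0.12 and -0.18, so its direction on DHA depends on how counts are averaged. Of 43 cornified envelope genes 0 passed, 0 adjusted over the list alone, with medians of 0.18 and 0.04. Of 2133 tested genes 0 passed edgeR's quasi-likelihood test for EPA against OD, DHA against OD, EPA against DHA or the 3 diets together. At unadjusted p under 0.05 there were 89, 46, 46 and 51 genes. DESeq2, limma with quality weights and limma on the deposited normalised values gave 0 in each.

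Matrix and fibroblast transcripts had lower means in the omega-3 skins without passing as individual genes. The proteoglycan Dcn averaged 837 ± 454 CPM on OD, 347 ± 319.5 on EPA and 299.7 ± 61.8 on DHA, log2 differences of -1.28 ± 0.42 and -1.54 ± 0.44. The adjusted p was 0.975 and 0.999 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The collagens Col1a2 and Col6a1 differed by -1.11 ± 0.51 and -1.24 ± 0.57 on EPA and -1.03 ± 0.51 and -1.87 ± 0.62 on DHA. Of 15 fibroblast members 0 passed on EPA (0 adjusted over the list alone, median -0.90) and 0 on DHA (1 lower adjusted over the list alone, median -0.90). The camera call at the preset correlation was lost on both (adjusted p = 0.3997 and 0.950 with an estimated correlation). Oxidative phosphorylation genes had medians of -0.27 and -0.18 over 65 members, 0 passing and 0 adjusted over the list alone (adjusted p = 0.591 and 0.950 with an estimated correlation). Hepatocyte transcripts had medians of 0.35 and 0.39 over 14 members in these skins, 0 passing and 0 adjusted over the list alone (adjusted p = 0.881 and 0.950 with an estimated correlation). Alb was at 842 ± 487 CPM on OD, 1352 ± 563 on EPA and 1402 ± 909 on DHA. Its counts were 44 to 99 per skin library whatever the total (Spearman correlation 0.0949 with the total, against a median of 0.880 over tested genes), so its CPM was higher where the total was lower (correlation -0.930). The 14 hepatocyte members together had 183 to 350 counts, and their CPM fell with the total in the same way (correlation -0.956). Their medians by diet therefore cannot be told apart from differences in depth. Without libraries under 60000 counts, a setting added after the results were seen, the DHA difference of Alb went from 0.70 to -0.09. The smallest p values on EPA belonged to Serpinb8 (1.13 ± 0.31), Manf (-0.95 ± 0.29), Gnb1 (-0.95 ± 0.30), Usmg5 (-1.12 ± 0.36) and Snrpe (-0.93 ± 0.31). On DHA they belonged to Dcn, Col6a1, Ppp2r1a (0.81 ± 0.27), Snrpe (-0.92 ± 0.31) and Lgals1 (-1.52 ± 0.52). For EPA against DHA they were Scpep1 (-1.44 ± 0.40), the ceramide synthase Cers3 (-0.71 ± 0.22), H2-Ab1 (-0.74 ± 0.25), Nectin4 (0.69 ± 0.23) and Chd7 (0.86 ± 0.30). The 95% interval of the difference EPA minus DHA was -0.53 to 0.60 in Krt14 and -1.19 to 0.34 in S100a8, so the fatty acids are not shown to act alike. The changes on EPA and on DHA had Pearson r = 0.64 and covariance 0.0741 across skin genes. Simulations without an effect and with genes drawn independently gave 0.54 (highest 0.589) and 0.0710. With 2 different OD libraries for each they were -0.02 and -0.00437. Without the filter on low counts 21, 13 and 3 genes passed in the pairwise comparisons and 32 over the 3 diets. Leaving out EPA skin 1 gave 4 genes for EPA against OD and 1 over the 3 diets. At this depth 28.4% of simulated 2-fold and 75.8% of 4-fold changes were recovered in skin, so the absence of calls leaves changes of that size open.

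In liver 0 of 5018 tested genes passed. Mup2 (ENSMUSG00000078688, GRCm38 chromosome 4, 60135932 to 60154289) is a major urinary protein secreted by hepatocytes. It averaged 12.3 ± 5.61 CPM on OD (SD, n = 4), 538 ± 369 on EPA and 817 ± 1213 on DHA (n = 5 each), log2 differences of 5.45 ± 0.99 and 6.05 ± 1.00. The adjusted p was 0.180 and 0.0660 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The Mup genes are near-identical, so reads cannot be assigned to each with certainty. On EPA and DHA the flavin monooxygenase Fmo2 differed by 1.76 ± 0.34 and 1.75 ± 0.35 and the lipase Abhd2 by 1.77 ± 0.35 and 1.41 ± 0.36. Ociad2 and the anion transporter Slc22a7 differed by -1.46 ± 0.30 and -1.31 ± 0.29 on EPA, and the metalloproteinase inhibitor Timp3 and the immunoglobulin gene Ighg2c by 1.18 ± 0.25 and 2.43 ± 0.58 on DHA. PPAR alpha targets, the genes that fatty acids induce for their own oxidation, had medians of 0.18 on EPA and 0.35 on DHA over 49 members. Of them 0 passed, 0 adjusted over the list alone (adjusted p = 0.625 and 0.492 with an estimated correlation). The omega-hydroxylases Cyp4a14 and Cyp4a10 were at 1.93 ± 0.75 and 1.25 ± 0.62 on EPA and 2.17 ± 0.75 and 1.60 ± 0.62 on DHA, and Cd36 at 1.20 ± 0.36 and 0.79 ± 0.37. Cholesterol synthesis genes had medians of -0.51 and -0.41 over 27 members, 0 passing and 0 adjusted over the list alone (adjusted p = 0.625 and 0.705 with an estimated correlation). Squalene epoxidase Sqle was at -1.61 ± 0.65 and -1.13 ± 0.62. Fatty acid synthesis genes had medians of -0.44 and -0.34 over 26 members, 0 passing and 0 adjusted over the list alone. Camera called this list on EPA at the preset correlation, and the call was lost (adjusted p = 0.521 with an estimated correlation). Thrsp was at -1.49 ± 0.43 on EPA, Fasn at -0.70 ± 0.55 and -0.85 ± 0.56 on EPA and DHA and the desaturase Fads1 at -0.44 ± 0.20 and -0.27 ± 0.20. Neither Cyp7a1 (-0.42 ± 0.57 and 0.45 ± 0.56) and Cyp8b1 (-0.95 ± 0.35 and 0.03 ± 0.33) of bile acid synthesis nor the carnitine palmitoyltransferase Cpt1a (0.04 ± 0.15 and 0.27 ± 0.15) passed. Srebf1 (-0.22 ± 0.43 and 0.07 ± 0.43) and Insig1 (-0.51 ± 0.29 and -0.52 ± 0.29) did not pass. Nor did Abca1 (-0.02 ± 0.20 and -0.12 ± 0.20), Elovl5 (-0.12 ± 0.36 and -0.11 ± 0.36), Fads2 (-0.66 ± 0.32 and -0.40 ± 0.31) or Apoa4 (-0.15 ± 0.45 and -0.66 ± 0.46). The acute phase gene Saa1 was at 1.02 ± 1.18 and -0.20 ± 1.15 without passing, at -0.96 on EPA without EPA liver 4 and at 0.95 on DHA without OD liver 1, so neither direction holds.

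Genes with sex-biased liver expression had 8 higher and 7 lower members of 21 on EPA adjusted over the list alone, and 5 higher and 2 lower on DHA. Among all genes 0 of them passed, and the libraries with high Xist are all on EPA or DHA. On EPA the median of this list was -0.80, its mean 0.81 and its direction in camera down, a call that was lost (adjusted p = 0.421 with an estimated correlation). Elovl3 was at -2.47 ± 0.64, Hsd3b5 at -2.93 ± 0.81 and Nudt7 at -1.38 ± 0.37. Hepatocyte genes had a median of -0.09 on EPA (adjusted p = 0.521 with an estimated correlation), gluconeogenesis genes -0.11 (adjusted p = 0.521 with an estimated correlation) and oxidative phosphorylation genes -0.10 (adjusted p = 0.625 with an estimated correlation). In these lists 0 members passed, 0 adjusted over the list alone, and the 3 directions turned when libraries were scaled by total counts alone. With that scaling the median change of all liver genes was 0.13 on EPA and 0.14 on DHA, against -0.01 and -0.00510 with TMM. By edgeR's quasi-likelihood test 0 genes passed for EPA against OD, DHA against OD, EPA against DHA or the 3 diets together, with 336, 309, 184 and 273 at unadjusted p under 0.05. DESeq2 gave 4, 2, 0 and 3, limma on the deposited normalised values 1, 1, 0 and 1, and limma with quality weights 0 in each. Between EPA and DHA the smallest p values belonged to the sphingolipid desaturase Degs1 (-0.66 ± 0.18), Sptbn1 (0.53 ± 0.15), Vps4b (-0.60 ± 0.17), Uba3 (-0.90 ± 0.26) and AW549877 (1.07 ± 0.32). The 95% interval of the difference EPA minus DHA was -1.56 to 1.08 in Cyp4a14 and -2.02 to 1.06 in Sqle, which leaves large differences open. The changes on EPA and on DHA had Pearson r = 0.77 and covariance 0.135 across liver genes. Simulations without an effect and with genes drawn independently gave 0.53 and 0.0574, so the excess does not show shared effects. With 2 different OD libraries for each they were 0.35 and 0.0873. Without the filter on low counts 131, 112, 40 and 159 genes passed, with the 3 tissues in a common fit 18, 3, 0 and 12, and without the libraries with high Xist 5, 0, 0 and 1. Leaving out DHA liver 3 or EPA liver 4 gave 1 gene each for EPA against OD and over the 3 diets, and leaving out DHA liver 2, 3 or 4 gave 1 gene each for DHA against OD. In liver 39.2% of simulated 2-fold and 88.5% of 4-fold changes were recovered.

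Whether a diet effect differed between tissues was tested in a common fit of the 9 groups over 9912 genes. Elovl3 (ENSMUSG00000038754, GRCm38 chromosome 19, 46131897 to 46135694) is an elongase of very long chain fatty acids expressed in brown fat, sebaceous glands and liver. Its EPA effect differed between tissues, at 1.52 in aorta, -2.52 in liver and 0.23 in skin (adjusted p = 0.00853 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its DHA effects were 1.63, -1.84 and 0.37, without passing (adjusted p = 0.0858 by the same test). Ociad2 had EPA effects of 1.56 in aorta, -1.51 in liver and 0.67 in skin (adjusted p = 0.0123 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 60 groupings of the libraries, the real one included, 3 gave as many as these 2 genes. Counts were low: Ociad2 had 0 to 4 per OD aorta and 4 to 9 per EPA aorta (22 to 62 and 6 to 12 in liver), and Elovl3 6 to 35 and 8 to 64 in aorta (10 to 70 and 0 to 12 in liver). For DHA against OD and for EPA against DHA 0 genes passed, with 725 and 308 at unadjusted p under 0.05 by edgeR's quasi-likelihood test. Limma with quality weights gave 67 and 0. In this fit 0 of the 319 genes called for DHA in aorta and 0 of the 18 called for EPA had an effect of that diet that differed. With libraries of the same diet and number taken as a mouse and the mouse as a block, a fit added after the results were seen, 8 genes passed for EPA, Elovl3 and Ociad2 among them, 5 for DHA and 0 for EPA against DHA. Those for DHA, named after their values were seen, were Mup2, Fmo2, Elovl3, Gpd1 and the transketolase gene Tkt, of which the last 3 are among the 319. For the others a difference of the aorta from the other tissues was not shown. Leaving out OD aorta 4 or OD liver 1 gave 0 genes for the EPA effect and leaving out EPA skin 1 gave 4. For DHA, leaving out OD aorta 2 gave 4, OD liver 2 gave 2, and EPA aorta 1, DHA aorta 1, OD liver 4, DHA liver 4, EPA liver 4 or EPA liver 5 gave 1 each. Without the libraries with high Xist Elovl3 still passed and Ociad2 did not (adjusted p = 0.157 by the same test).

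**Figure D4:**
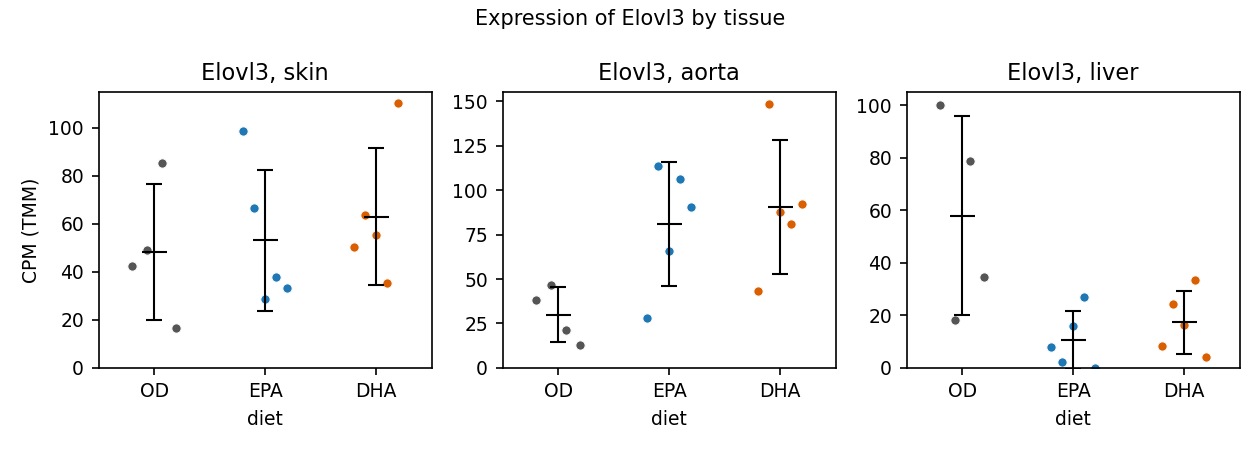
Expression of Elovl3 (y axis, CPM scaled by TMM) by diet (x axis) in skin, aorta and liver, with 1 point per library and bars at the mean ± SD, drawn down to 0 where an SD would pass below it. In liver it averages 57.95 CPM on OD and 10.6 on EPA, and in aorta 29.9 and 80.9.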

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

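The lists and genes screened here were fixed in advance, but which lists entered the screen for libraries far from the rest of the group was set by their results. Of 285 sets of values within a group, 12 held a library far from the others by Dixon's ratio, where chance gives 5%. EPA aorta 1 was lowest in its group in the mean log2 CPM of the oxidative phosphorylation list (8.73 against 9.11 to 9.22 in the other EPA aortas), the sebaceous gland list (6.99 against 7.48 to 7.64) and the gluconeogenesis and insulin response list (5.87 against 6.40 to 6.55). OD skin 1 was highest in Rac1, at 4706 against 1282 to 1469 CPM in the other OD skins. DHA skin 1, at 4068 against 787 to 1974 CPM in the other DHA skins, was not flagged by this ratio. OD liver 3 was lowest in the macrophage and monocyte list mean (5.43 against 5.89 to 5.95). The acute phase genes Saa1 and Saa2 were highest in OD liver 1 (5499 against 820.0 to 999 and 3136 against 202 to 435 CPM) and in EPA liver 4 (16718 against 96.9 to 3678 and 11966 against 35.6 to 2223 CPM). EPA liver 2 was far from its group in the mean of the sex-biased liver list (5.69 against 6.10 to 6.20) and in Apoa4 (1105 against 164 to 385 CPM), and DHA liver 1 in Elovl6 (89.8 against 28.0 to 42.9 CPM).

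Elovl3 and Ociad2 had EPA effects that differed between tissues by the interaction test (adjusted p = 0.00853 and 0.0123, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with fitted values on either side of 0 in aorta and liver, at 0 to 4 counts of Ociad2 per OD aorta.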

How the results depend on the processing

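The settings without the libraries with high Xist, with Xist status or the brown adipocyte list as a covariate, with thinned counts, without mitochondrially encoded genes, without libraries under 60000 counts, and the exact permutation of list means were chosen after results had been seen. Counts in this part are of genes past the threshold, in the order EPA against OD, DHA against OD, EPA against DHA and the 3 diets together where 4 are given; the cause was not tested unless stated. Between diets, which were fed to different mice, libraries cannot be paired. Between tissues, the replicate block, which takes libraries of the same diet and number as a mouse and was also added after results had been seen, gave 8 genes whose EPA effect differed (2 without it), 5 for DHA (0 without it) and 0 for EPA against DHA; it was run for these results alone.

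Without the filter the counts were 21, 13, 3 and 32 in skin, 131, 112, 40 and 159 in liver and 257 for EPA, 12 for EPA against DHA and 409 for the 3 diets in aorta. The aortic EPA count of 18 became 186 with DESeq2, 85 with a robust prior, 192 with quality weights, 8 on the deposited normalised values, 4 with the tag number as a block, 1 in the fit of 42 libraries, 0 with 2 diets in the fit, 100 without the libraries with high Xist, 29 with Xist status as a covariate, 0 with thinned counts, 0 with the brown adipocyte covariate and 170 at adjusted p under 0.1. The aortic DHA count of 319 became 116 in the fit of 42 libraries, 188 with thinned counts, where depth is lower by construction, and 0 with the brown adipocyte covariate, and stayed within 1.5 times otherwise. The aortic count of 165 over the 3 diets became 285 with quality weights, 57 with the tag block, 28 in the fit of 42 libraries, 76 with thinned counts, 0 with the brown adipocyte covariate and 304 at adjusted p under 0.1. In liver DESeq2 gave 4, 2 and 3 for EPA, DHA and the 3 diets, limma on the deposited normalised values 1, 1 and 1, and the fit of 42 libraries 18, 3 and 12; for EPA there were 1 with 2 diets in the fit, 5 without the libraries with high Xist (1 for the 3 diets) and 6 with Xist status as a covariate, and for DHA 1 at adjusted p under 0.1.

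With the OD libraries divided 2 and 2 between the contrasts, the correlation of EPA and DHA changes was -0.0203 in skin, 0.32 in aorta and 0.35 in liver; this ends the sharing and also leaves fewer controls per contrast, and the effects of these were not separated. Genes whose EPA effect differed between tissues numbered 1 with a robust prior and 29 with quality weights, and for DHA 67 with quality weights, 13 among genes passing the filter in each tissue, where fewer are tested, 2 without the libraries with high Xist and 1 at adjusted p under 0.1. List calls over all comparisons numbered 2 with an estimated correlation, 20 with fry and 11 by exact permutation, against 64 at the preset correlation. In aorta EPA lists numbered 1 with an estimated correlation, 8 with fry and 0 by exact permutation, DHA lists 1 with an estimated correlation, and EPA against DHA lists 0, 0 and 0, with 8 without the filter and 1 without the libraries with high Xist. In skin and liver every list call was lost, at 0 by each of these tests, and EPA against DHA in skin had 2 without the libraries with high Xist. With the brown adipocyte covariate the change of Acsl1 in DHA aortas turned to -0.0105. Of the other values of named genes outside the sets with a library left out, 5413 stayed on their side of the threshold (134 of them, from genes passing in neither fit, with a turned sign), 202 lost the threshold and 234 gained it.

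With a library left out at a time, counts ranged over 0 to 4, 0 to 0, 0 to 0 and 0 to 1 in skin, 0 to 257, 70 to 374, 0 to 0 and 5 to 288 in aorta, and 0 to 1, 0 to 1, 0 to 0 and 0 to 1 in liver. The correlations ranged over 0.53 to 0.73, 0.71 to 0.84 and 0.66 to 0.82 in skin, aorta and liver, and genes with effects that differed between tissues over 0 to 4, 0 to 4 and 0 to 0. List calls for EPA, DHA and EPA against DHA ranged over 4 to 8, 1 to 6 and 0 to 4 in skin, 12 to 20, 12 to 15 and 3 to 10 in aorta and 5 to 12, 4 to 11 and 4 to 8 in liver. Of the values of named genes with a library left out, 5645 stayed on their side of the threshold, 236 lost it and 68 gained it. Of those that stayed, 152 had a turned sign, from genes passing in neither fit. Recovery of simulated 1.5-fold changes was lowest in skin, at 7.81%, where depth is lowest and the biological coefficient of variation highest (0.274, against 0.185 in aorta and 0.259 in liver); these were not separated.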

Other observations

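The tests of explanations and of other groupings in this part were chosen after the results were seen. In liver, transcripts of plasma cells, the cells that secrete antibodies, had higher means on both fatty acids without passing: Ighg1 was at 1.48 ± 0.55 on EPA and 1.71 ± 0.55 on DHA (log2 ± SE, n = 4 and 5), Jchain, which joins IgA and IgM, at 0.85 ± 0.55 and 1.503 ± 0.53, and Ighg2c on DHA at 2.43 ± 0.58. The B and plasma cell list had 0 of 5 members passing and medians of 0.86 and 1.503, with 0 and 5 higher adjusted over the list alone (adjusted p = 0.479 and adjusted p = 0.327 with an estimated correlation). The unfolded protein response list, chaperones of the secretory pathway among them, had medians of -0.23 on EPA and -0.32 on DHA over 21 members, 0 passing and 0 and 6 lower adjusted over the list alone (adjusted p = 0.625 and adjusted p = 0.365 with an estimated correlation), with the disulfide isomerases Pdia3 at -0.67 ± 0.20 and -0.64 ± 0.20 and Pdia4 at -0.32 ± 0.18 and -0.67 ± 0.18, Hsp90b1 at -0.57 ± 0.16 on DHA and the transcription factor Xbp1 at -0.64 ± 0.20 on DHA. Between EPA and DHA the macrophage and monocyte list had a median of -0.37 over 15 members, 0 passing and 0 adjusted over the list alone (adjusted p = 0.779 with an estimated correlation), with Tyrobp at -1.09 ± 0.40 and the Kupffer cell receptor Vsig4 at -0.86 ± 0.33. Ribosomal protein genes had medians of 0.10 and 0.11 on EPA and DHA over 78 members, 0 passing and 0 adjusted over the list alone (adjusted p = 0.625 and adjusted p = 0.705 with an estimated correlation).

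In skin on EPA the genes of antigen presentation H2-Aa and Cd74 were at -0.54 ± 0.37 and -0.45 ± 0.23, the detoxification genes Gpx3, Gsta4 and Mgst1 at -1.35 ± 0.57, -1.09 ± 0.56 and -0.64 ± 0.34, and Lpl and Apoe of lipid transport at -0.82 ± 0.50 and -0.35 ± 0.22, none of them passing (adjusted p = 0.975 each by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Their lists had medians of -0.45 (dendritic and Langerhans cells, 5 members), -0.38 (NRF2 and glutathione, 14) and -0.54 (LXR targets, 7), with 0 passing and 0 adjusted over each list alone (adjusted p = 0.429, 0.400 and 0.400 with an estimated correlation). In DHA skins the skeletal muscle list had a median of -0.20 over 16 members in the fit (-0.93 as the median of differences in mean log2 CPM) and the immediate early list -0.26 over 13, 0 passing and 0 adjusted over each list alone (adjusted p = 0.950 for each with an estimated correlation). In aorta Vcam1, an adhesion molecule of activated endothelium, was at -0.95 ± 0.23 on EPA (adjusted p = 0.0628 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and -0.69 ± 0.23 on DHA (adjusted p = 0.0888), without passing.

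The rise of oxidative, lipogenic and brown adipocyte genes in DHA aortas may reflect more brown adipocytes in the samples rather than a change within vessel cells, as a hypothesis. With the brown adipocyte list mean as a covariate 0 of 319 calls remained and their median change went from 0.81 (median SE 0.19) to 0.35 (median SE 0.26), with 304 keeping their sign; for EPA it went from 0.97 to 0.59. The remaining change exceeds its standard error and the covariate itself follows diet, so this test cannot tell the explanations apart. More skeletal muscle alone does not account for it in DHA aortas, since 204 of the 319 genes passed with the skeletal muscle list mean as a covariate, with a median of 0.80 (median SE 0.20); for EPA 6 of the 18 passed, at a median of 0.95 (from 0.97), and this stays open. For a lower share of smooth muscle alone a rise of the fibroblast list was predicted, and its median was -0.28. That list also holds extracellular matrix genes, which smooth muscle cells can make too. Its fall therefore cannot decide this, and the explanation stays open. The unequal number of libraries with high Xist is not supported as the cause, since 273 genes passed without them.

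The fall of immediate early and heat shock genes in DHA aortas could be a dilution by adipocyte RNA or a difference in stress at collection, as hypotheses. With the brown adipocyte covariate the list mean still differed by -0.55 ± 0.14 (from -0.61 ± 0.09, log2 CPM, SE). This speaks against a dilution that follows the brown adipocyte list alone. The covariate itself follows diet and is not a measure of white adipocyte RNA, so dilution by adipocyte RNA in general is not excluded. The list means were also lower in skin, by 0.09 on EPA and 0.25 on DHA, and in liver, by 0.32 and 0.23, without passing (smallest exact permutation p = 0.127). The list member Dusp1 was at 29.8 to 47.5 CPM (TMM) in OD livers, 10.0 to 18.3 in EPA livers and 11.2 to 30.3 in DHA livers. In skin Dusp1 was at 73.4 to 385 on OD, 28.8 to 155 on EPA and 35.2 to 117 on DHA. Cyr61 and Nr4a1 had at most 13 counts in any skin or liver library. A difference in stress or handling at collection, in every tissue or in the aortas alone, therefore stays open.

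Mup2 lay at 4.66 to 16.4 CPM in the OD livers and at 114 to 2897 CPM in the EPA and DHA livers. The unequal number of libraries with high Xist is unlikely to account for this, since the lowest EPA or DHA liver without them was at 114 CPM. A fixed share of reads of the other Mup genes counted as Mup2 is excluded as the cause, since Mup2 made up at most 0.0201% of all Mup counts in the OD livers and at least 0.198% in each EPA or DHA liver, and 0 of the other 20 Mup genes had a higher mean on EPA and DHA. A difference in the Mup genes themselves between mice, which could change where reads align, was not tested and stays open.

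To ask how often other groupings of the same libraries give as many calls, the libraries of the diets compared were regrouped in 100 ways, the real one included, or in 60 ways for differences between tissues. In aorta as many genes as in the real grouping were called in 1 (real 319, highest other 4) for DHA, 4 (real 18, highest other 281) for EPA, 100 (real 0, highest other 3) for EPA against DHA and 2 (real 165, highest other 395) for the 3 diets; the 281 and 395 genes are many more than the real groupings gave, and which libraries were exchanged in them was not examined. In skin the numbers were 100 (real 0, highest other 6), 100 (real 0, highest other 29), 100 (real 0, highest other 3) and 100 (real 0, highest other 27) for EPA, DHA, EPA against DHA and the 3 diets, and in liver 100 (real 0, highest other 1), 100 (real 0, highest other 2), 100 (real 0, highest other 26) and 100 (real 0, highest other 29). For differences between tissues they were 3 (real 2, highest other 2) for EPA, 60 (real 0, highest other 3) for DHA and 60 (real 0, highest other 3) for EPA against DHA, of 60, redrawn in each tissue apart without regard to the mouse. The number of genes for EPA is thus one that other groupings also gave. List calls at the preset correlation arose as often in 18 (real 15, highest other 19), 30 (real 12, highest other 19) and 78 (real 3, highest other 13) groupings in aorta, 41 (real 6, highest other 15), 43 (real 5, highest other 16) and 100 (real 0, highest other 13) in skin and 7 (real 11, highest other 12), 37 (real 6, highest other 10) and 51 (real 6, highest other 12) in liver, so the number of lists called is no more than other groupings give.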
